A study of Mus musculus with 8 samples.

How the data were processed

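Lineage-negative, c-Kit and Sca-1 positive cells (LSK) and megakaryocyte and erythroid progenitors (MEP) were sorted 2 months after transplantation of marrow of 4 genotypes into irradiated wild-type recipients. Ezh2 was deleted 4 weeks after transplantation. From each of the 8 groups 20 ng of RNA was labelled with Cy3 and hybridized to 1 one-colour Agilent mouse array. All 8 arrays lie on 1 slide with 1 scan, where the row is the cell type and the column the genotype, so slide position cannot be separated from the groups.

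The scanner files as deposited hold intensity values, made per the file headers with Agilent Feature Extraction 10.7.1.1, which subtracted the background and detrended each array without normalizing between arrays. The series table deposited by the authors holds a linear ratio, which on the values is the processed signal divided by a factor per array near its 75th percentile, with an SD of the log2 difference of at most 0.00779 within an array. Each array had 62976 spots, of which 3671 were controls, and 55681 probes. The files pair probes with RefSeq accessions, and these were matched to symbols with a table of assembly GRCm38.p6, used for names and chromosomes alone. Of the probes 27509 (49.4%) matched a gene and 28172 did not, and the matched ones covered 20887 genes.

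Processed signals were averaged over the spots of a probe without non-uniform spots, put on the log2 scale and reduced by the 75th percentile of the array. A gene was read from its probe with the highest mean signal, and it was tested when that probe was well above background, by the flag of Feature Extraction, on at least 2 of 8 arrays, which left 13199 genes. Where some or all arrays of the dimmer group were below background, their values were raised to the lowest signal well above background on the array, and the fold of a named gene was given as a lower bound. SE and p come from the fit, which uses the values as measured. The number of arrays limits the precision.

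Effects were fitted with limma 3.58.1 in R 4.3.3. An additive fit of cell type, JAK2 genotype and Ezh2 genotype gave the Ezh2 deletion effect, the JAK2V617F effect and the difference between MEP and LSK, each averaged over 4 matched pairs of arrays, with interactions counted as spread. Coefficients nested in the cell type gave the effects within LSK and MEP and their difference. The nested fit pools the spread between pairs over both cell types, so an SE within LSK is not the spread of the LSK pairs alone. An added interaction tested whether the Ezh2 effect depended on JAK2V617F. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Single arrays were compared by counts of genes at least 2-fold apart, with no test. The 22 gene lists were tested with camera at a preset correlation of 0.01 between genes, with p adjusted over the lists, and for single arrays by the percentile of the list median among 10000 random lists matched on expression. Alternatives to camera were an estimated correlation and the rotation test fry, which asks whether a list moves one way and does not compare it with other genes.

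The comparisons, the gene lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule names Ezh2 and Jak2, up to 12 called genes each way for the 2 main effects that moved the same way in all 4 pairs, and up to 8 each way for MEP against LSK. It names up to 8 genes each way within a cell type, among those at least 2-fold apart in both pairs and ranked by the smaller fold, up to 6 each way for the double mutant against WT, up to 5 for each interaction, and up to 4 members of a list with those past the threshold. Some genes that the rule picks are not reported here. Other settings were normexp background correction, quantile normalization, the series table, other filters on dim probes, keeping non-uniform spots, averaging the probes of a gene, a variance prior with a trend, an adjusted p under 0.10, other fold thresholds, the average of the nested coefficients, and leaving out each array. Normexp used the median spot signal, since the mean signal is not in the files. A common floor, the use of probes without a gene, and leaving out the X and Y genes were added after seeing the data.

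The fits were tested on simulated data of 13195 genes with 50 changed genes at each of 4 sizes. For the Ezh2 effect 19 of 50 were recovered at a log2 change of 1, 43 at 2, 46 at 3 and 49 at 4, with 8 false calls. For the effect within LSK 0, 15, 34 and 46 were recovered with 5 false calls, and for the interaction of both genotypes 1, 13, 31 and 40 with 4 false calls. A simulated list of 20 genes raised by 1 was called with an estimated correlation (adjusted p = 0.00560), and 0 of 20 unchanged lists were. The simulated genes varied independently of each other, so this does not show what that test can find in genes that vary together.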

Results

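Gene expression was measured in 2 haematopoietic progenitor fractions of mice reconstituted with bone marrow of 4 genotypes. Marrow was wild type (WT), Ezh2-deleted, JAK2V617F or double mutant, the last carrying JAK2V617F and the Ezh2 deletion together. Ezh2 is the catalytic subunit of the polycomb repressive complex PRC2, which silences genes by methylating histone H3, and JAK2V617F is the activated kinase found in myeloproliferative neoplasms. LSK cells are the Lineage-negative, c-Kit and Sca-1 positive fraction that holds the stem cells, and MEP are the megakaryocyte and erythroid progenitors. Each of the 8 groups had 1 array, so no group has a replicate of its own, and effects were averaged over matched pairs of arrays. Between 39.8% and 48.8% of the probes on an array were well above background, and 13199 genes were tested. Arrays of one cell type correlated at 0.961 to 0.981, and arrays of different cell types at 0.885 to 0.925. The first principal component, with 67.1% of the variance, parted LSK from MEP. Levels are log2 signal relative to the 75th percentile of the array, fold changes are log2 unless said to be -fold, errors are standard errors (SE) of the fit, and p-values are adjusted over all genes unless said otherwise.

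The Ezh2 probe was well above background in all groups and was lower with deletion in each of the 4 matched pairs. Its level in LSK was 3.33 in WT, 3.20 with Ezh2 deleted, 3.65 with JAK2V617F and 3.41 in the double mutant, and in MEP it was 3.97, 3.86, 4.04 and 3.43. The fold change with deletion was -0.27 (SE 0.17, n = 4 against 4, adjusted p = 0.404). Which exon the probe reads is not known from the files, so these levels check nothing about the deletion. Jak2, read by 1 probe, was at 2.55 in WT LSK and 2.16 in JAK2V617F LSK, and at 3.07 and 3.17 in the matching MEP, with a fold change of -0.30 over all pairs (SE 0.17, adjusted p = 0.573). The sex-linked genes divided the arrays by Ezh2 status. Xist, the RNA that coats the inactive X chromosome, was between 1.39 and 2.85 on the 4 Ezh2-deleted arrays and at most -3.23 on the 4 others. Eif2s3y, a translation factor gene on the Y chromosome, was between 2.36 and 3.39 on the Ezh2-intact arrays and below background on all Ezh2-deleted ones. Marrow sex and Ezh2 status therefore changed together on all 8 arrays, and every Ezh2 difference given here is also a difference between the sexes of the marrow.

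LSK and MEP served to check that the arrays read the sorted fractions. Rhd, which carries the Rh blood group antigen, was at least 672-fold higher in MEP (SE 0.27, n = 4 against 4, adjusted p = 2.8e-06), and the carbonic anhydrase gene Car1 was 283-fold higher. Flt3, the receptor of lymphoid and early myeloid progenitors, was at least 170-fold lower in MEP, and Ly6a, which encodes Sca-1 itself, was at least 88.4-fold lower (SE 0.31). With limma 2735 genes were higher in MEP and 2683 lower, and 6771 genes had an unadjusted p under 0.05. Other genes far higher in MEP were Slc38a5 (298-fold), Sphk1 (227-fold), Col5a1 (at least 213-fold), Cldn13 (at least 183-fold), Add2 (at least 145-fold) and Slc25a21 (at least 117-fold). Far lower were Wfdc17 (at least 106.6-fold), Dntt (at least 162-fold), Ccl3 (at least 73.8-fold), Mcpt4 (at least 43.0-fold), Robo4 (at least 36.4-fold) and Cd53 (at least 25.9-fold). Of these, Rhd and Col5a1 were above background on 1 of the 4 LSK arrays, and Ly6a and Wfdc17 on 1, Ccl3 on 2 and Dntt on 3 of the 4 MEP arrays. Of 29 erythroid genes 25 were higher in MEP, with a list median of 4.14 (camera adjusted p = 1.0e-12, adjusted p = 0.374 with an estimated correlation). Of 22 stem cell genes 15 were lower (list median -1.38, camera adjusted p = 2.4e-05, adjusted p = 0.374 with an estimated correlation), and of 15 lymphoid priming genes 13 were lower (list median -2.29, camera adjusted p = 2.1e-07, adjusted p = 0.289 with an estimated correlation). Megakaryocyte genes had a median of 0.50 and were not called (camera adjusted p = 0.474).

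Ezh2 deletion went with more signal from 87 genes, among them Vpreb3 and Blnk of the B lineage and the fetal gene Hmga2. Vpreb3, which pairs with the pre-B cell receptor, was at least 40.9-fold higher on the Ezh2-deleted arrays (SE 0.66, n = 4 against 4, adjusted p = 0.0132). Blnk, the adapter of B cell receptor signalling, rose 6.85-fold (log2 2.78, SE 0.24, adjusted p = 0.00602). Hmga2, a chromatin protein of fetal stem cells, was at least 3.06-fold higher (SE 0.29, adjusted p = 0.0132), and it was above background on all 4 Ezh2-deleted arrays and on 2 of the 4 others. In all, limma called these 87 genes higher and 6 lower. At an unadjusted p under 0.05 there were 2405 genes, 1062 higher and 1343 lower, against 660 expected by chance. This wider set thus leaned lower, and the median fold change of all genes was -0.10. Each of the 93 called genes moved the same way in all 4 pairs. The fit favours such agreement, since it counts disagreement between pairs as spread, and pairs below background on both sides were counted too. Of these, 5 lie on the X and 3 on the Y chromosome, and 85 are autosomal, 82 higher and 3 lower. In 24 of the 93, one side was below background on all its arrays, so that their fold is a lower bound. The count changed with the array left out. In LSK it was 103 without WT, 55 without Ezh2-deleted, 59 without JAK2V617F and 26 without the double mutant. In MEP it was 78, 69, 17 and 13 in that order. Such fits lose balance and residual degrees of freedom, so a lower count alone does not show that calls rest on 1 array. The count was 7 when dim values were raised to a common floor, which also lowered the median prior and residual degrees of freedom from 7.59 to 5.18. Of the 93 genes 22 were above background on all 8 arrays.

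Most of the other named genes called higher with Ezh2 deletion were below background on some of the 4 Ezh2-intact arrays. Fndc4, a secreted fibronectin-domain protein, was at least 8.56-fold higher (SE 0.44, adjusted p = 0.00972). The X-linked genes Rps6ka6, a ribosomal S6 kinase, Bex2, an adapter first described in brain, and Pwwp3b, a chromatin reader, were at least 8.62-fold, 12.7-fold and 3.52-fold higher. Mpped2, a phosphodiesterase, was at least 5.92-fold higher. These 5 genes were above background on 1 of the 4 Ezh2-intact arrays. The malic enzyme Me1, above background on 2 of them, was at least 4.50-fold higher, and Plagl1, an imprinted zinc finger gene that restrains growth, above background on 3 of them, was at least 8.59-fold higher. The last of these depends on the probe, since 1 other Plagl1 probe gave 3.01 and a pair of others gave 0.26. Mzb1, an antibody-assembly factor of B and plasma cells, was at least 5.92-fold higher, and Pou2af1, the B cell co-activator of octamer promoters, was at least 3.76-fold higher with 2 of the 4 Ezh2-deleted arrays above background. Fxyd6, a subunit of the sodium pump, was at least 2.88-fold higher. Lower genes other than the Y-linked Eif2s3y, Ddx3y and Uty were Tox4, a high-mobility-group protein (6.72-fold, SE 0.27, adjusted p = 0.0105), the homeobox gene Hoxb2 (at least 3.33-fold, adjusted p = 0.0397) and Ajuba, a LIM-domain scaffold (at least 1.68-fold, adjusted p = 0.0456), above background on 3 and 2 of the 4 Ezh2-deleted arrays. A second Tox4 probe gave -0.25, against -2.75 for the probe used. Bmi1, a subunit of the sister complex PRC1, was 2.56-fold higher (adjusted p = 0.0132) by 2 probes at 1.36 and 1.49, and it is named here after its values were seen.

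**Figure D1:**
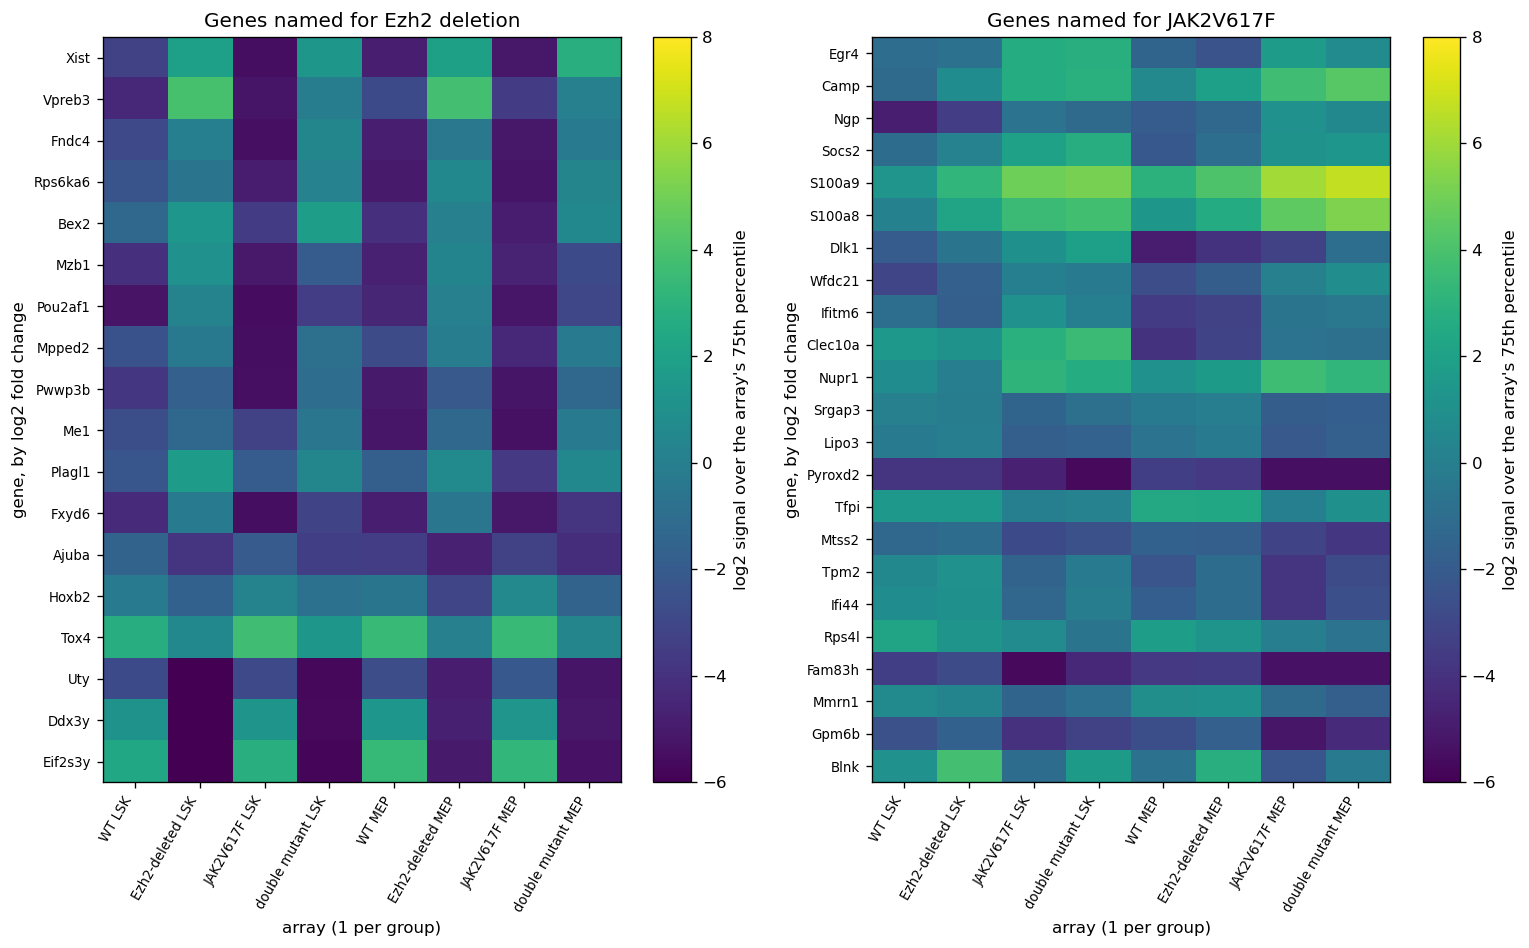
Log2 signal relative to the 75th percentile of the array (colour) of named genes (rows) called for Ezh2 deletion and for JAK2V617F on each of the 8 arrays (columns, 1 per group). Vpreb3 and Pou2af1 were at 3.94 and 0.28 in Ezh2-deleted LSK and at -4.43 and -5.29 in WT LSK.

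Gene lists moved broadly with Ezh2 deletion, and none of these calls held when the correlation between the genes of a list was estimated. B cell genes were higher by a median of 2.82 (6 of 6 positive, 2 called over all genes, 5 adjusted over the list alone; camera adjusted p = 8.4e-06, adjusted p = 0.229 with an estimated correlation). Ebf1, which was below background in WT, reached -0.81 in Ezh2-deleted LSK and -1.53 in Ezh2-deleted MEP and stayed below background in both double mutants (-4.08 and -5.21). Lymphoid priming genes had a median of 1.29 (14 of 15 positive, 1 called over all genes, 8 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.4e-06, adjusted p = 0.221 with an estimated correlation), with Vpreb1 at 3.31 and Blnk at 2.78. Dntt was at least 6.91-fold apart and Igll1 at least 5.88-fold, above background on 3 and 1 of the 4 Ezh2-intact arrays. T and NK cell genes had a median of 0.57 (camera adjusted p = 0.0266, adjusted p = 0.269 with an estimated correlation), with Gzma, a granzyme, called (at least 2.09-fold, adjusted p = 0.0222). Granulocyte genes had a median of 0.25 with 0 called over all genes (camera adjusted p = 0.0266, adjusted p = 0.663 with an estimated correlation), and the cell types differed. Their median was -0.32 in LSK (8 of 16 negative, camera adjusted p = 0.255) and 0.66 in MEP, and between single LSK arrays it was 0.11 for Ezh2-deleted over WT and -1.02 for the double mutant over JAK2V617F, where 9 genes were at least 2-fold lower and 0 higher. With dim values raised to a common floor the B cell and lymphoid priming medians were 1.00 and 0.85 and stayed called, while the T and NK cell and granulocyte calls ended (camera adjusted p = 0.143 and 0.119) and the granulocyte median turned to -0.15. Monocyte, mast cell, megakaryocyte, erythroid and stromal genes were not called (camera adjusted p = 0.603, 0.877, 0.603, 0.671 and 0.288).

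Fetal and oncofetal genes had a median of 1.18 with Ezh2 deletion (6 of 8 positive, 1 called over all genes, 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.7e-04, adjusted p = 0.269 with an estimated correlation; median 0.66 with a common floor). Lin28b, which blocks let-7 maturation in fetal stem cells, was above background in the double mutants alone, at -0.61 in LSK and 0.23 in MEP. Over all pairs it was at least 2.91-fold apart (adjusted p = 0.0609), with 0 of the 4 Ezh2-intact arrays above background. Afp was at 1.42, and Dlk1 was at least 1.76-fold apart, above background on 2 of the 4 Ezh2-intact arrays. The developmental regulators silenced by PRC2 had a median of 0.12 (9 of 12 positive, 0 called over all genes or adjusted over the list alone; camera adjusted p = 0.0559). Its member Cdkn2a, a cell cycle inhibitor, was at least 2.51-fold apart (adjusted p = 0.159), above background on 2 of the 4 Ezh2-intact arrays. Of the 14 Hox genes measured Hoxb2 was lower and none was called higher. The other PRC2 subunits had a median of -0.10, and their folds ran from -0.44 for Mtf2 to 0.18 for Aebp2 (camera adjusted p = 0.539).

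Stress and signalling lists were also higher with Ezh2 deletion. The p53 targets had a median of 0.36 (camera adjusted p = 7.6e-04, adjusted p = 0.221 with an estimated correlation), and 3 of 15 were called, Perp at 1.81 (SE 0.22, adjusted p = 0.0200), Fas at least 2.28-fold higher (adjusted p = 0.0249) and Phlda3 at 1.07 (adjusted p = 0.0427). TNF and NF-kB response genes had a median of 0.44 (17 of 20 positive, 0 called over all genes; camera adjusted p = 3.4e-04, adjusted p = 0.439 with an estimated correlation), with Cd83 at 1.88. JAK-STAT targets had a median of 0.29 with 0 called over all genes (camera adjusted p = 0.00941, adjusted p = 0.439 with an estimated correlation), with Id1 at 1.42. TGF-beta pathway genes had a median of 0.42 with 0 called over all genes (camera adjusted p = 0.0266, adjusted p = 0.491 with an estimated correlation). Cell cycle genes were lower by a median of -0.32 (24 of 26 negative, 0 called over all genes; camera adjusted p = 0.00687, adjusted p = 0.663 with an estimated correlation), with Plk1 at -0.60 and Bub1b at -0.59. Stem cell, interferon and immediate early genes were not called (camera adjusted p = 0.288, 0.252 and 0.708). For the megakaryocyte, monocyte, mast cell and immediate early lists the median is negative while camera gives the direction as up. The sex-linked list was called lower (camera adjusted p = 5.3e-04, adjusted p = 0.229 with an estimated correlation), its median of -4.74 resting on the 3 Y-linked genes.

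JAK2V617F went with more signal from granule genes such as S100a9 and from the STAT5 target Socs2, and with less of the platelet gene Mmrn1 and of Blnk. S100a9, a calprotectin subunit of neutrophils, rose 6.91-fold (log2 2.79, SE 0.26, n = 4 against 4, adjusted p = 0.0177). Socs2, the feedback inhibitor that STAT5 induces, rose 7.04-fold (log2 2.82, SE 0.21, adjusted p = 0.0135), with the same value from 2 other probes (2.86 and 2.81). Mmrn1, the factor V carrier of platelet granules, fell 4.11-fold (log2 -2.04, SE 0.25, adjusted p = 0.0274). In all, limma called 27 genes higher and 14 lower with JAK2V617F. At an unadjusted p under 0.05 there were 1465 genes, 689 higher and 776 lower, against 660 expected by chance, so this wider set leaned slightly lower. All 41 called genes moved the same way in all 4 pairs, which the fit favours here as well. In 5 of the 41, one side was below background on all its arrays. Leaving out 1 LSK array gave 12 genes without WT, 15 without Ezh2-deleted, 31 without JAK2V617F and 44 without the double mutant. Leaving out 1 MEP array gave 17, 5, 1 and 0 in that order, and these fits lose balance and residual degrees of freedom too. With dim values raised to a common floor limma called 0 genes, with the lowest adjusted p at 0.0675. The floor also lowered the median prior and residual degrees of freedom from 7.59 to 5.18. Of the 41 genes 20 were above background on all 8 arrays, so the loss does not mean that all calls rest on dim values. When only genes above background on all 8 arrays were tested, limma called 116, with 20 of the 41 among them.

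The zinc finger gene Egr4 rose 10.4-fold with JAK2V617F (log2 3.38, SE 0.26, adjusted p = 0.0135). Further granule genes were Camp, the cathelicidin (7.26-fold, a second probe at 2.71), Ngp (at least 6.32-fold) and S100a8 (6.43-fold). Dlk1, an imprinted Notch-like ligand of fetal tissues, was at least 3.36-fold higher, although its second probe gave 1.45. Wfdc21 (at least 5.70-fold), Ifitm6 (at least 4.38-fold), the macrophage lectin Clec10a (at least 4.08-fold) and the stress-induced Nupr1 (4.92-fold) were also higher. Of these, Ngp and Wfdc21 were above background on 3 of the 4 JAK2 wild-type arrays, and Dlk1, Ifitm6 and Clec10a on 2. Among lower genes Blnk fell 4.61-fold (log2 -2.21, SE 0.24, adjusted p = 0.0177). The proteolipid Gpm6b (at least 2.21-fold), Rps4l (3.33-fold), the interferon-induced Ifi44 (at least 2.87-fold), the tropomyosin Tpm2 (at least 2.83-fold), Mtss2 (at least 2.78-fold), the coagulation inhibitor Tfpi (3.01-fold), the lipase Lipo3 (2.83-fold) and Srgap3 (2.70-fold) were lower too. Of the 4 JAK2V617F arrays Gpm6b was above background on 1, Mtss2 on 2, and Ifi44 and Tpm2 on 3. The other Srgap3 probe had the opposite sign (0.22). Fam83h was at least 1.03-fold lower, and Pyroxd2 was measured on 2 of the 4 JAK2 wild-type arrays and on none with JAK2V617F. The genes called for Ezh2 deletion as well were Blnk, Il18r1, an interleukin 18 receptor chain, and Plek2, a pleckstrin of the JAK2 pathway. Blnk moved in opposite directions, while Il18r1 was at least 1.91-fold and 2.91-fold higher and Plek2 at least 2.05-fold and 2.94-fold, for Ezh2 deletion and JAK2V617F. A second Il18r1 probe gave smaller log2 folds of 0.89 and 0.79, against 1.23 and 1.96 for the probe used.

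Granulocyte and neutrophil genes had the largest shift of any list with JAK2V617F, with a median of 2.39 and 16 of 16 positive (camera adjusted p = 1.2e-19, adjusted p = 0.199 with an estimated correlation). Over all genes 5 were called, Camp, Ngp, S100a8, S100a9 and Chil3 (2.27), and 13 were called when adjusted over the list alone. Mpo, the myeloperoxidase of primary granules, was at 8.95 in WT LSK and 10.51 in JAK2V617F LSK, and at 2.18 and 5.14 in the matching MEP. Monocyte genes had a median of 0.83 (12 of 13 positive, 1 called over all genes, 3 adjusted over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.245 with an estimated correlation; median 0.27 with a common floor), the called gene being the fractalkine receptor Cx3cr1 at 2.08 (adjusted p = 0.0443). Mast cell genes had a median of 0.61 (camera adjusted p = 0.00102, adjusted p = 0.199 with an estimated correlation), with the IgE receptor chain Fcer1a called at 2.25 (adjusted p = 0.0212) and 3 adjusted over the list alone. TNF and NF-kB response genes had a median of 0.62 (19 of 20 positive; camera adjusted p = 4.9e-08, adjusted p = 0.245 with an estimated correlation), with Il6 called (at least 3.57-fold, adjusted p = 0.0413) and 6 adjusted over the list alone.

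JAK-STAT targets had a median of 0.31 with JAK2V617F (camera adjusted p = 0.00108, adjusted p = 0.325 with an estimated correlation), and besides Socs2 the podocalyxin gene Podxl was at least 5.73-fold apart (adjusted p = 0.0957), above background on 1 of the 4 JAK2 wild-type arrays. Immediate early genes had a median of 0.47 (11 of 11 positive, 0 called over all genes; camera adjusted p = 0.00102, adjusted p = 0.382 with an estimated correlation). The p53 targets had a median of 0.22 with 0 called over all genes (camera adjusted p = 0.0131, adjusted p = 0.199 with an estimated correlation), with Pmaip1 at 2.16. The developmental regulators had a median of 0.33, and 0.16 with a common floor (10 of 12 positive, 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.199 with an estimated correlation). Among them Cdkn2a was at least 5.87-fold apart (adjusted p = 0.0739) and Cdkn2b at least 1.19-fold, above background on 2 and 1 of the 4 JAK2 wild-type arrays. Megakaryocyte genes had a median of -0.56 (19 of 24 negative, Mmrn1 called over all genes, 3 lower adjusted over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.361 with an estimated correlation). Interferon response genes had a median of -0.36 (Ifi44 called over all genes, 7 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.2e-04, adjusted p = 0.325 with an estimated correlation), while their member Cxcl10 was at 1.61.

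Lymphoid priming genes had a median of -0.69 with JAK2V617F (12 of 15 negative, Blnk called; camera adjusted p = 1.9e-04, adjusted p = 0.199 with an estimated correlation) and B cell genes one of -1.58 with 0 called over all genes (camera adjusted p = 0.0338, adjusted p = 0.382 with an estimated correlation). In LSK the B cell fall lay between the Ezh2-deleted arrays, with a median of -3.04 for the double mutant over Ezh2-deleted. With Ezh2 intact the B cell median for JAK2V617F over WT was 0.50 in LSK and -0.27 in MEP. There 2 of the 6 genes were above background in WT LSK and 2 in WT MEP, so most could not be seen to fall. TGF-beta pathway genes had a median of -0.53 (camera adjusted p = 0.0114, adjusted p = 0.361 with an estimated correlation). Stem cell genes had a median of -0.32 (camera adjusted p = 0.0332, adjusted p = 0.452 with an estimated correlation), with Hlf, a transcription factor of quiescent stem cells, at -1.43 and the endothelial guidance receptor Robo4 at least 1.52-fold lower, above background on 2 of the 4 JAK2V617F arrays. With a common floor the B cell and stem cell calls ended (camera adjusted p = 0.103 and 0.0723) and the lymphoid priming median was -0.29. Erythroid genes were not called as a list (median 0.12, camera adjusted p = 0.243), although the tropomodulin Tmod1 was at least 2.75-fold higher (adjusted p = 0.0463). PRC2 subunit, Hox, fetal, T and NK cell, stromal and cell cycle lists were not called (camera adjusted p = 0.357, 0.880, 0.0514, 0.0674, 0.438 and 0.827). No camera call for any effect, in both cell types together or in one, held with an estimated correlation. That includes the erythroid genes for MEP against LSK, so a call lost this way does not show that a list stayed unchanged. The rotation test fry called p53 targets and sex-linked genes for Ezh2 deletion and the developmental and granulocyte lists for JAK2V617F.

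**Figure D2:**
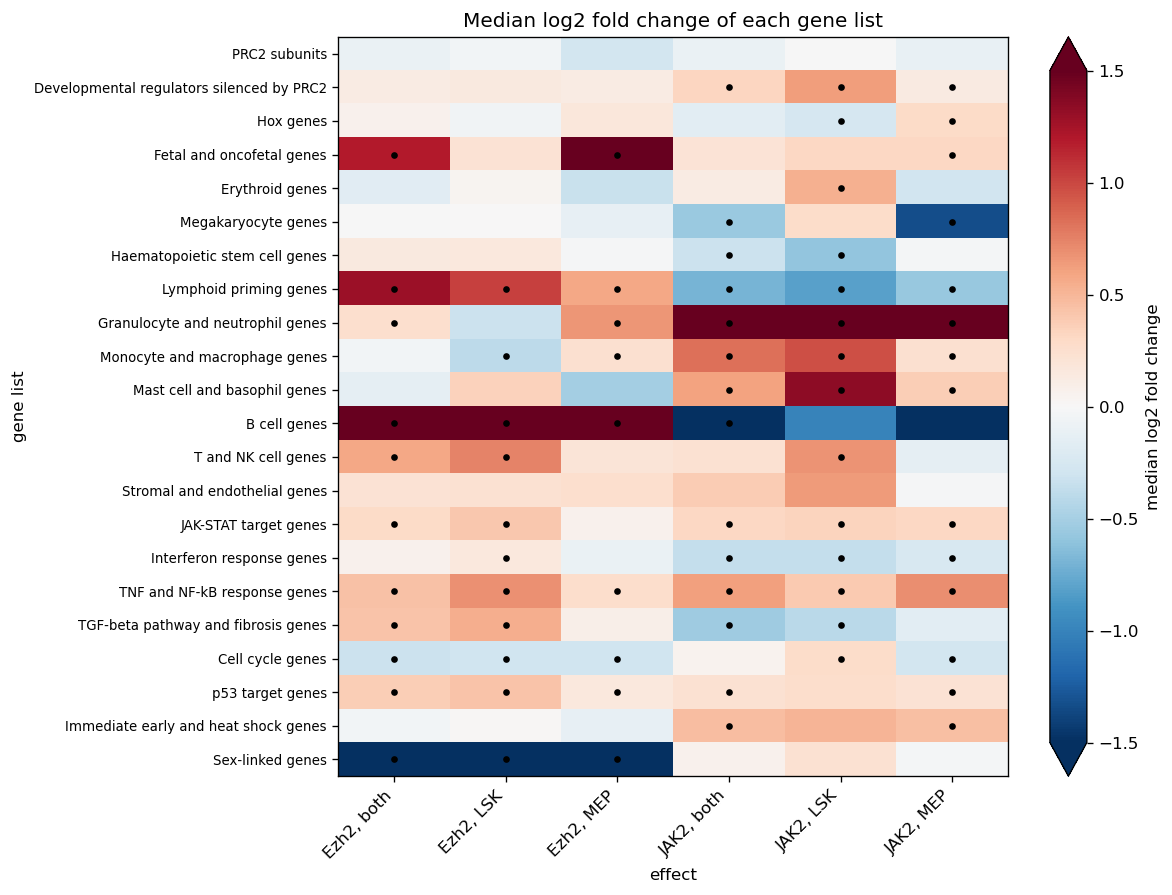
Median log2 fold change (colour, limited to 1.5 either way) of each of the 22 gene lists (rows) for Ezh2 deletion and JAK2V617F over both cell types and in each (columns), dots marking camera adjusted p under 0.05. Megakaryocyte genes had medians of 0.27 in LSK and -1.33 in MEP with JAK2V617F.

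Within LSK the Ezh2 effect rests on 2 matched pairs, while its SE also draws on the spread between the MEP pairs. Leaving out an MEP array therefore changes the calls within LSK but not the LSK folds. In LSK limma called 16 genes higher and 4 lower (1262 with an unadjusted p under 0.05). In 14 of the 20, one group was below background on all its arrays, and the count was 0 with dim values raised to a common floor, 2 with no filter on dim probes and 55 with normexp. Of the 16 genes that were at least 2-fold apart in both pairs and ranked first, 5 passed the test. Wnt10b, a Wnt ligand, was at least 6.75-fold higher in Ezh2-deleted LSK (SE 0.20, n = 2 against 2, adjusted p = 0.0260), as was Xist (at least 32.8-fold), while Tox4 fell (log2 -2.25, SE 0.21, adjusted p = 0.0456) with Eif2s3y and Ddx3y. The remaining 11 missed the threshold. Among these, Ly6d, the marker of B-primed lymphoid progenitors, was at least 6.93-fold apart in both pairs (adjusted p = 0.0690), Blnk at least 6.49-fold (adjusted p = 0.0991), the vesicle GTPase Rab15 at least 6.28-fold (adjusted p = 0.0696) and Vpreb3 at least 10.8-fold (adjusted p = 0.107). Hk3, the hexokinase of myeloid cells, was at least 3.38-fold lower in both pairs (adjusted p = 0.107). Fndc4, Bex2, Creb3l3, Ajuba, Crygc and Aldh3b1 complete the set. Over the genome 205 genes were at least 2-fold higher in both LSK pairs and 31 lower, against 21.2 and 2.89 expected from independent pairs, and the folds of the pairs correlated at 0.494. The lists called higher in LSK included TGF-beta pathway genes (median 0.54, camera adjusted p = 1.1e-04, adjusted p = 0.475 with an estimated correlation) and p53 targets (median 0.43, camera adjusted p = 2.2e-04, adjusted p = 0.475 with an estimated correlation). Monocyte genes were called lower (median -0.40, camera adjusted p = 0.0284, adjusted p = 0.475 with an estimated correlation). These contrasts too follow the sex of the marrow. The count was 273 without the WT or the Ezh2-deleted LSK array, 115 without the JAK2V617F or the double mutant LSK array and 0 without any 1 of the 4 MEP arrays, in fits with 1 residual degree of freedom.

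Within MEP limma called 60 genes higher and 20 lower with Ezh2 deletion (1734 with an unadjusted p under 0.05), and 12 of the 16 named genes passed the test. In 57 of the 80 calls one group was below background on all its arrays, and the count was 0 with the common floor and 2 with no filter. Bex1, an X-linked signalling adapter, rose 21.8-fold (log2 4.45, SE 0.49, n = 2 against 2, adjusted p = 0.0360). Echdc2, a mitochondrial hydratase, rose 10.9-fold (log2 3.44, SE 0.23, adjusted p = 0.00983), and the zinc transporter Slc30a4 was at least 10.4-fold higher in both pairs. Dntt, the terminal transferase of lymphoid progenitors, was at least 8.54-fold higher in both (adjusted p = 0.0483). Tox4 fell 9.51-fold (log2 -3.25, SE 0.21, adjusted p = 0.00983), Hoxb2 was at least 4.41-fold lower, and Tmprss11d, Hes3 and Lama1 were at least 3.40-fold, 3.14-fold and 3.13-fold lower in both pairs (adjusted p = 0.00983 each). Rps6ka6, Vpreb3, Bex2 and Bglap2 missed the threshold (adjusted p = 0.0590, 0.145, 0.0676 and 0.0529). There were 150 genes at least 2-fold higher in both MEP pairs and 29 lower, against 17.0 and 8.85 expected, and 35 and 5 genes were shared with LSK among those measured in both. The folds of the pairs correlated at 0.274. Fetal genes had a median of 1.99 in MEP (2 called over all genes, 6 adjusted over the list alone; camera adjusted p = 3.9e-05, adjusted p = 0.535 with an estimated correlation). Granulocyte genes had one of 0.66 (14 of 16 positive, 0 called over all genes; camera adjusted p = 1.7e-05, adjusted p = 0.658 with an estimated correlation). Marrow sex again goes with every one of these differences. Without any 1 of the 4 LSK arrays 401 genes were called, and without any 1 of the 4 MEP arrays 0 were.

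**Figure D3:**
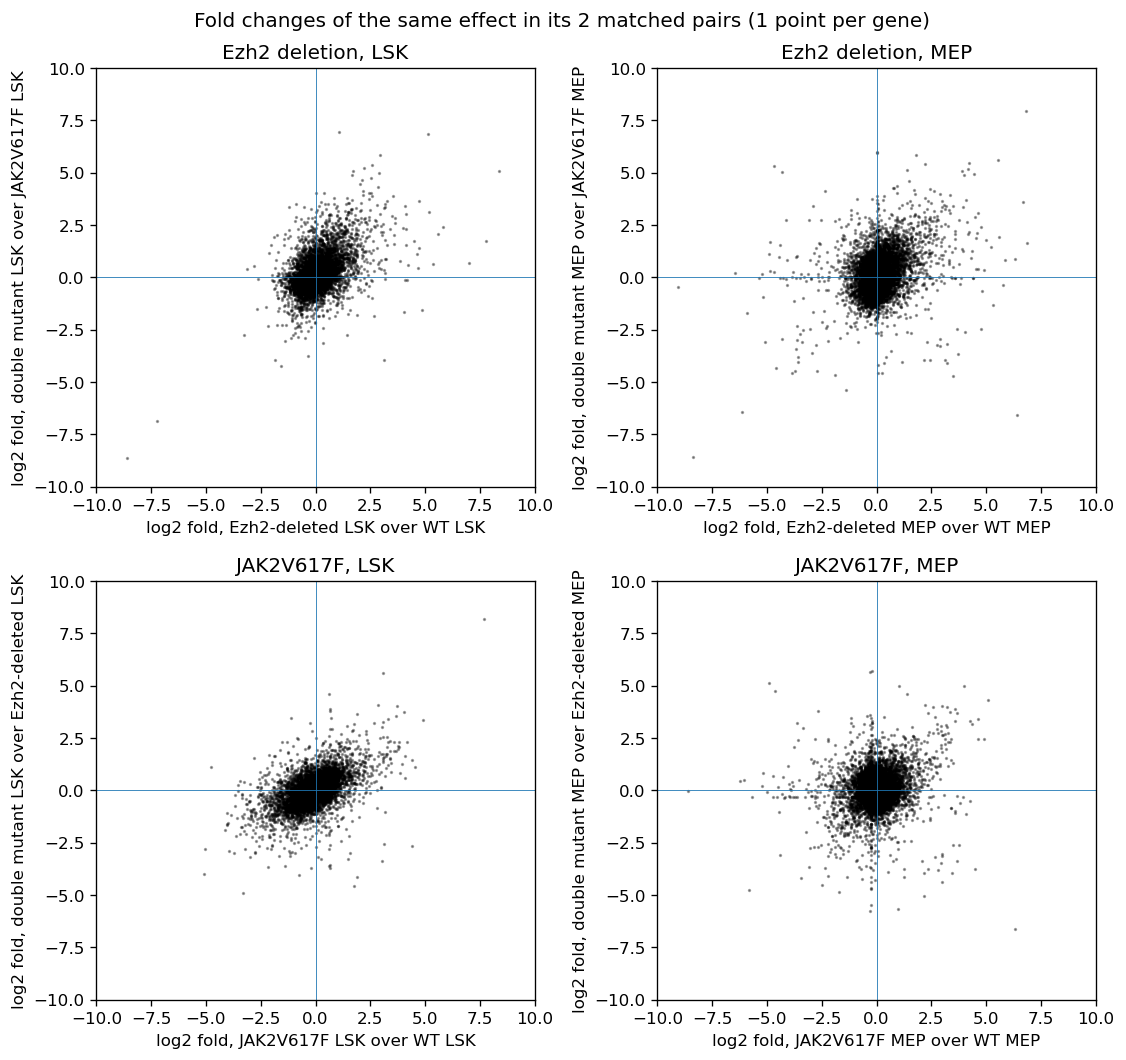
Log2 fold change of each of the 13199 genes (points) in the first matched pair of arrays against the second, for Ezh2 deletion and JAK2V617F in LSK and in MEP. The correlations were 0.494 and 0.274 for Ezh2 deletion and 0.672 and 0.103 for JAK2V617F, taken across the 10475 genes above background on all arrays, which are not independent replicates.

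JAK2V617F within LSK gave 8 higher and 11 lower genes with limma (2366 with an unadjusted p under 0.05), and 9 of the 16 genes ranked by the smaller fold passed. Of the 19 calls 12 had one group below background on all its arrays, and the count was 0 with the common floor, 0 with no filter and 225 with normexp. Alox5, the 5-lipoxygenase of myeloid cells, rose 9.06-fold (log2 3.18, SE 0.20, n = 2 against 2, adjusted p = 0.0220). Egr4 and the scramblase Plscr2 rose as well (adjusted p = 0.0169 and 0.0283), and Podxl was at least 7.37-fold higher in both pairs (adjusted p = 0.0456). The sialomucin Emcn, a marker of stem cells and endothelium, was at least 6.32-fold lower in both pairs (adjusted p = 0.0266), the helicase Ddx4 at least 7.91-fold and the trafficking protein Dennd2a at least 5.60-fold (adjusted p = 0.0266 each), and the dehydrogenase Bdh2 fell 5.20-fold (adjusted p = 0.0399). Socs2, Dlk1 and Ccr2 above, and Ramp3, Hnf4a, S1pr1 and Dcaf12l1 below, were past 2-fold in both pairs and missed the threshold (adjusted p from 0.0556 for Ccr2 to 0.131 for Hnf4a). There were 173 genes higher in both LSK pairs and 160 lower, against 13.05 and 14.8 expected, and the folds correlated at 0.672. Stem cell genes were lower (median -0.59, 6 adjusted over the list alone; camera adjusted p = 6.1e-04, adjusted p = 0.518 with an estimated correlation) and erythroid genes higher (median 0.54, 22 of 29 positive; camera adjusted p = 0.00409, adjusted p = 0.461 with an estimated correlation). Hlf went from 3.80 in WT to 0.81 in JAK2V617F LSK, and Robo4 from 2.89 to 0.03. The stem cell fall was larger in this pair, with a median of -0.83 and 0 genes at least 2-fold higher and 9 lower. For double mutant over Ezh2-deleted LSK the median was -0.35, with 2 higher and 3 lower. The gene count was 117 without the WT or the JAK2V617F LSK array, 297 without the Ezh2-deleted or the double mutant LSK array and 0 without any 1 of the 4 MEP arrays.

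In MEP JAK2V617F gave 15 higher and 5 lower genes with limma (1051 with an unadjusted p under 0.05), and 3 of the 16 named genes passed. Of the 20 calls 17 had one group below background on all its arrays, and the count was 0 with the common floor, 0 with no filter and 54 with normexp. Mpo rose 8.06-fold (log2 3.01, SE 0.27, n = 2 against 2, adjusted p = 0.0372) and Egr4 8.88-fold (adjusted p = 0.0242), and the crystallin Crygs was at least 10.4-fold lower in both pairs (adjusted p = 0.0269). Further granulocyte genes missed the threshold, with cathepsin G, Ctsg, at least 6.71-fold higher in both pairs (adjusted p = 0.0553), haptoglobin, Hp, at least 6.20-fold (adjusted p = 0.0651) and the granulocyte regulator Cebpe at least 5.78-fold (adjusted p = 0.0683). S100a8, S100a9 and Wfdc21 were past 6-fold in both pairs too (adjusted p = 0.108, 0.102 and 0.102). Megakaryocyte genes were lower too without passing gene by gene. The platelet chemokine Ppbp was at least 4.71-fold lower in both pairs (adjusted p = 0.102), the fibrinogen receptor chain Itgb3 4.68-fold (adjusted p = 0.0751), the caveolar protein Cavin2 4.71-fold (adjusted p = 0.0683) and Mmrn1 4.19-fold (adjusted p = 0.0810). Wnt2b, Igll1 and Gstm2 complete the lower set (adjusted p = 0.0893, 0.596 and 0.0775). As a list the megakaryocyte genes had a median of -1.33 (21 of 24 negative, 0 called over all genes, 16 adjusted over the list alone; camera adjusted p = 3.1e-16, adjusted p = 0.422 with an estimated correlation). Von Willebrand factor, Vwf, went from 5.12 in WT MEP to 3.61 with JAK2V617F and 1.96 in the double mutant. In MEP 87 genes were higher in both pairs and 86 lower, against 7.43 and 5.89 expected, 38 and 14 were shared with LSK, and the folds correlated at 0.103. The gene count was 339 without any 1 of the 4 LSK arrays and 0 without any 1 of the 4 MEP arrays.

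Differences between the effects were tested directly. The Ezh2 effect differed between the cell types for 1 gene, 6330403K07Rik, named after its values were seen (adjusted p = 0.0338; limma, 707 genes with an unadjusted p under 0.05 against 660 expected). One side of each of its 4 pairs was below background. With those values raised to the lowest signal well above background on the array its fold with deletion was 1.78 in LSK and -0.38 in MEP, so the difference is at least 2.16 in size. The JAK2V617F effect differed between the cell types for 0 genes with limma (1528 with an unadjusted p under 0.05), with the lowest adjusted p at 0.141. Whether the Ezh2 effect depended on JAK2V617F was tested with limma too, and 0 genes passed (459 with an unadjusted p under 0.05, lowest adjusted p = 0.182), against 11 without the WT LSK array and 4 without the WT MEP array. The cell type difference in the Ezh2 effect gave 138 genes without the WT or the Ezh2-deleted LSK array, 83 without the JAK2V617F or the double mutant LSK array and 0 without any 1 of the MEP arrays. That in the JAK2V617F effect gave 85 without the WT or the JAK2V617F LSK array and 156 without the Ezh2-deleted or the double mutant LSK array. As lists, megakaryocyte genes differed between the cell types in their response to JAK2V617F (median difference -1.23, camera adjusted p = 3.2e-08, adjusted p = 0.707 with an estimated correlation), as did erythroid genes (median difference -0.67, camera adjusted p = 2.7e-04, adjusted p = 0.707 with an estimated correlation). Immediate early genes and B cell genes had a lower Ezh2 effect with JAK2V617F than without (median differences -1.31 and -3.07, camera adjusted p = 1.6e-11 and 1.5e-07, adjusted p = 0.158 each with an estimated correlation). Vpreb3 shows the second of these, at 3.94 in Ezh2-deleted LSK and -0.10 in double mutant LSK.

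Double mutants were compared with WT array by array, without a test. In LSK 717 genes were at least 2-fold higher and 287 lower, and in MEP 707 and 594. Single mutants had fewer in MEP, with 367 and 184 for Ezh2 deletion and 296 and 288 for JAK2V617F, and in LSK they had 511 and 202, and 466 and 582. Against JAK2V617F alone the double mutant had 568 higher and 196 lower genes in LSK, and 677 and 671 in MEP. Against Ezh2 deletion alone it had 409 and 349 in LSK, and 375 and 327 in MEP. Cdkn2a, which encodes p16 and p19 and arrests the cell cycle, was below background in WT LSK and WT MEP and at least 16.2-fold and 13.4-fold higher in the double mutants. It stood at -1.59 in both Ezh2-deleted fractions, at -0.35 in JAK2V617F LSK, and at -0.15 in double mutant LSK and 0.84 in double mutant MEP. Among the largest increases in LSK were Xist (24.7-fold), the endothelial proteoglycan Esm1 (at least 20.7-fold), recoverin, Rcvrn (at least 18.7-fold), the actin regulator Enah (at least 17.1-fold) and Vpreb3 (at least 16.8-fold). The largest decreases after Eif2s3y and Ddx3y were Wfdc2 (at least 10.2-fold), Dcaf12l1 (7.37-fold), Rps4l (6.94-fold) and Dennd2a (at least 6.21-fold).

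In double mutant MEP the largest increases over WT were Xist (at least 54.4-fold), Ctsg (22.2-fold), Bex1 (21.6-fold), Catsperz (at least 19.2-fold), Mpo (18.8-fold) and Echdc2 (15.7-fold). The largest decreases besides Eif2s3y and Ddx3y were Orc5 (539-fold), Rapgef5 (at least 47.6-fold), Mafg (33.2-fold) and Rbm44 (at least 29.8-fold). Orc5, Rapgef5 and Mafg were bright on the WT MEP array alone, where 10 genes were at least 16-fold brighter than on the other 3 MEP arrays, and the other 2 Mafg probes were not raised there. Among lists, granulocyte genes had a median fold of 1.68 in LSK and 2.74 in MEP (the 100th percentile of 10000 random lists in both). Megakaryocyte genes had one of -1.19 in MEP (0th percentile), with 12 of 24 at least 2-fold lower, and fetal genes one of 3.00 in MEP (100th percentile). Stem cell genes had a median of -0.42 in LSK (0.13th percentile) and interferon genes one of -0.45 (0.11th percentile).

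**Figure D4:**
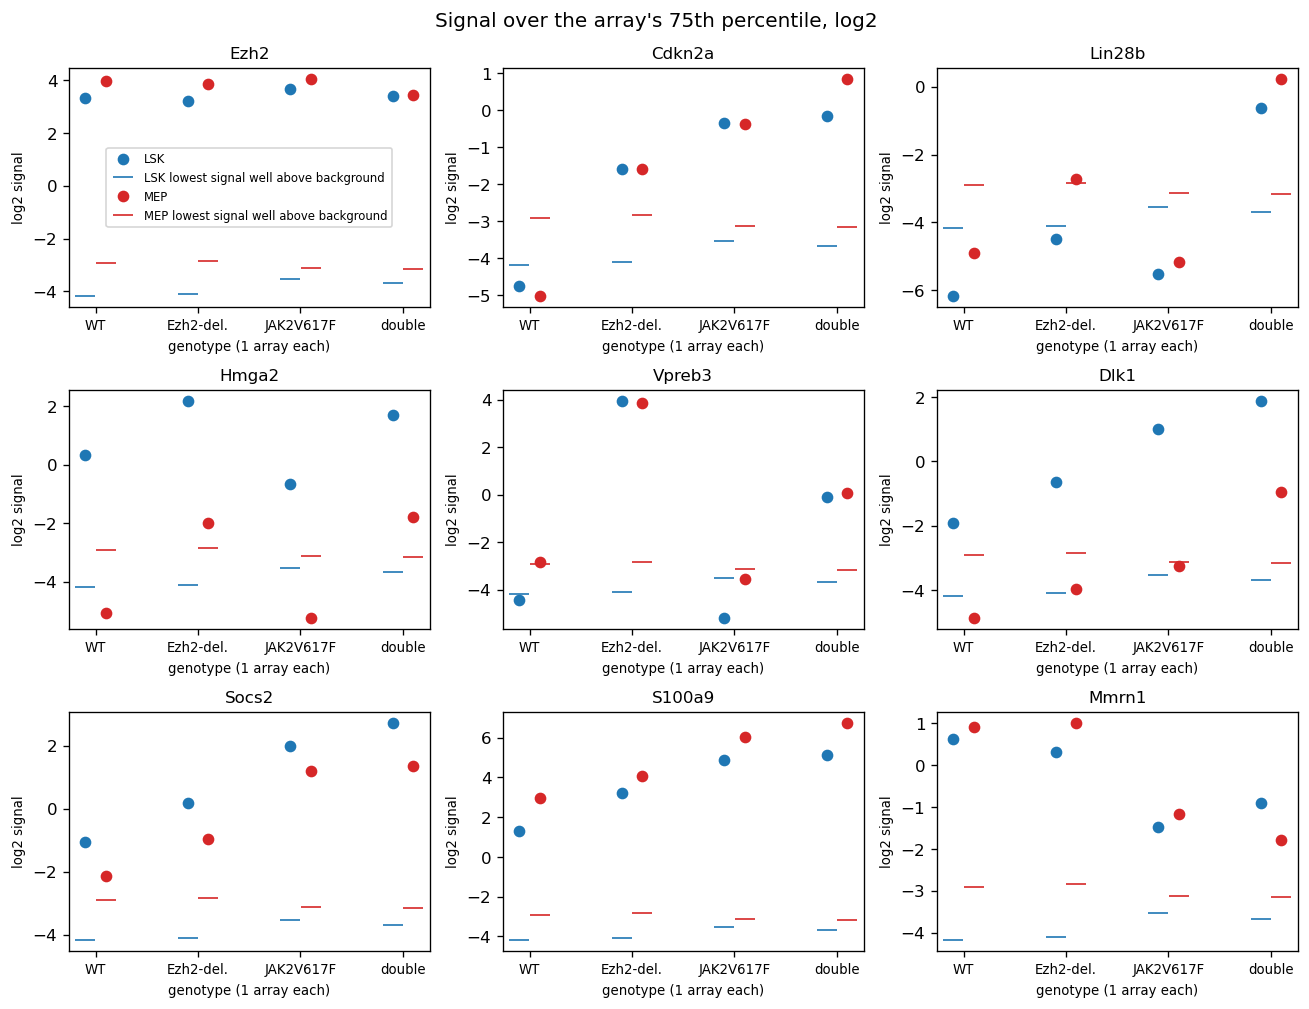
Log2 signal relative to the 75th percentile of the array (vertical axis) for 9 genes in the 4 genotypes (horizontal axis), 1 point per array, LSK in blue and MEP in red, with a dash at the lowest signal well above background. Cdkn2a was below the dash in WT and above it in the other genotypes, and Lin28b was clear of it in the double mutants, at -0.61 and 0.23.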

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

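All tests in this part were chosen only after the result was seen, except the counts over all other splits of the arrays and the test of the difference between cell types.

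The Ezh2 effect on 6330403K07Rik differed between the cell types in the fit (log2 difference -5.55, SE 0.29, adjusted p = 0.0338), which used values below background. With these raised to the floor of the array the difference is -2.16, which bounds its size from below. In LSK its level was -5.06 in WT and -5.47 with JAK2V617F, both below background, and -1.95 and -2.18 in the Ezh2-deleted and double mutant arrays. In MEP it was -2.50 and -2.73 with Ezh2 intact, and -4.82 and -5.13, both below background, with Ezh2 deleted. The direction held in both pairs of each cell type. No explanation was tested for it, and the sex of the marrow changes with Ezh2 status here too.

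Chance as the source of the gene counts was tested by fitting other splits of the 8 arrays into 4 and 4, of which 33 of 35 could be fitted. For Ezh2 deletion 1 of 33 splits, the real one, gave as many genes (93, against at most 2 for another split). For JAK2V617F it was again 1 of 33 (41, against at most 3), and for MEP against LSK 1 of 33 (5418, against at most 0). Each fit kept the other 2 factors as terms, and most of these splits are unbalanced over them, which lowers their precision. Only 9 splits are balanced as the real one is, and of these 1 gave as many genes for each effect, with at most 2, 1 and 0 genes for another split. With 9 splits the share cannot be under 0.05. In the other splits any difference by the replaced factor stays in the residual, which widens the spread and lowers their counts, most of all for MEP against LSK.

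The first pattern is the set of 93 genes called for Ezh2 deletion, 87 of them higher. Brighter Ezh2-deleted arrays were considered as a source. Over both cell types 87.5% of the calls were higher with quantile normalization, which gives the arrays 1 distribution. It changed the Ezh2 effect over all genes by a median size of 0.11. Folds with a median size of 2.06 could hardly turn that way, so this share decides nothing about brighter arrays. The number of calls did fall, from 87 higher to 42. The 93 genes kept their direction, with a median size of fold of 1.95 against 2.06 and a median SE of 0.25 against 0.24. Within LSK the 20 calls became 2, with 0 of the 16 higher ones left. The median size of fold of the 20 was 2.89 against 3.11 and the median SE 0.23 against 0.23, with all 20 in the same direction. Their median unadjusted p went from 2.8e-05 to 8.5e-05, with fewer median prior and residual degrees of freedom (5.03 against 5.55), and their median adjusted p of 0.0973 then missed the threshold. With dim values raised to the floor of each array, 90.6% of the median fold of the 16 was left (1.95 against 2.15). Over all genes, though, quantile normalization changed the LSK effect by a median size of 0.09. A fold of 2.15 could hardly be lost that way, so the share left decides nothing about brighter arrays as its source. Within MEP 31 of the 53 calls with quantile normalization were higher (58.5%, against 75%), and 30 of the 60 higher calls were kept. Brighter arrays could lower the share in this way, but the Ezh2-deleted MEP arrays were not brighter by every measure. Their 75th percentile signal was 219.74 against 242.52 in WT, and 233.30 in the double mutant against 263.98 with JAK2V617F. Their median signal was lower than in WT in the first of these pairs and higher than with JAK2V617F in the second. The lower share therefore decides nothing about brighter arrays in MEP. The median size of fold of all 80 called genes was 2.84 against 2.73, with a median SE of 0.23 against 0.24. Their median unadjusted p went from 9.7e-05 to 1.2e-04, with the same loss of degrees of freedom. With dim values raised, 93.8% of the median fold of the 60 was left (1.45 against 1.55). Quantile normalization changed the MEP effect over all genes by a median size of 0.13, so this share decides nothing in MEP either. Sequence carried along with the floxed gene on chromosome 6 is argued against as the main source, since 1 autosomal call lies on chromosome 6, where 4.57 calls would fall by gene number. Sex of the marrow was read from Xist, Eif2s3y, Ddx3y and Uty themselves, so that these part the Ezh2 groups on 8 of 8 arrays tests nothing. For the 85 autosomal genes, sex and Ezh2 deletion cannot be told apart, because no array of either Ezh2 status comes from marrow of the other sex. Loss of silencing by PRC2 and a sex difference may both contribute, and the design leaves both open.

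The second pattern is the rise of granulocyte genes with JAK2V617F. If granulocytes in the sorted fractions were the source, the added linear signal of their genes would keep 1 ratio between genes in every pair. The test could use only values above background that rose at least 2-fold, in genes with at least 2 of them, which favours 1 source. For primary and later granule genes together the residual SD of the log2 excess after gene and pair terms was 1.64 over 50 values of 13 genes, with 14 values and 3 genes left out. That is over the bound of 1 in spite of the choice, and argues against 1 such source for the whole list. For the later granule genes it was 0.684 over 28 values of 7 genes, with Csf3r and Mmp8 left out because they rose in at most 1 pair. The low value decides nothing, so carry-over of mature granulocytes may or may not be the source for these. The sort on Lineage-negative cells would remove mature granulocytes. Of the 16 genes 13 were above background in WT LSK and 13 in WT MEP. S100a9 rose by 2.79, and Mpo was at 8.95 in WT LSK and 10.51 in JAK2V617F LSK. A myeloid bias of the progenitors themselves stays open and was not tested.

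The third pattern is the rise of B-lineage genes with Ezh2 deletion. The residual SD was 0.352 over 11 values of 4 genes with 4 residual degrees of freedom. That test left out 13 values that were below background, rose less than 2-fold or were the only such rise of a gene, among them all of Cd79b and Cd22 and the double mutant values of Ebf1 and Pou2af1. It decides nothing, and B-lineage cells in the sorted fractions may or may not be the source. Cd79b, at 3.80 in WT LSK, differed by 0.15 and -0.29 in the LSK pairs and by 2.25 and 0.37 in the MEP pairs. The levels of Vpreb3 were 3.94 in LSK and 3.84 in MEP with Ezh2 deleted, nearly alike in fractions that otherwise differ widely, and -0.10 in double mutant LSK. The same gate would remove B cells that carry a lineage marker. Of the 6 genes 2 were above background in WT LSK and 2 in WT MEP. Expression in the progenitors and the sex of the marrow stay open as untested explanations.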

How the results depend on the processing

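Tests with a common floor, with probes that have no gene name, and without X and Y genes were chosen only after the result was seen. For every change listed here the cause was not tested, unless the setting itself shows it. The series table, non-uniform spots kept and the mean of the probes left all gene counts within 1.5 times their value. Raising dim values to a common floor (log2 -2.84) removes fold below that level and lowered the median prior and residual degrees of freedom from 7.59 to 5.18. A looser threshold and fewer tested genes change counts by construction.

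For Ezh2 deletion the 93 genes became 48 with quantile normalization, 51 with no filter on dim probes, 182 with a trended variance prior, 226 at an adjusted p under 0.10, 169 with the average of the nested coefficients and 7 with the common floor. Leaving out 1 array gave 13 to 103. For JAK2V617F the 41 genes became 101 with normexp, 27 with quantile normalization, 116 when only genes above background on all 8 arrays were tested, 18 with no filter, 122 with the trend, 115 at 0.10, 118 with the nested average and 0 with the floor, and 0 to 44 with 1 array left out. MEP against LSK gave 9814 genes with no filter, against 5418. The called genes changed as well as their number. For Ezh2 deletion normexp called 130 genes, 58 of them among the 93, and quantile normalization kept 46. On genes above background everywhere 106 were called, 23 of them among the 93, most of which that filter leaves untested. For JAK2V617F 31 of the 101 with normexp and 20 of the 116 above background everywhere were among the 41.

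Within LSK the 20 genes for Ezh2 deletion became 55 with normexp, 2 with quantile normalization, 48 on genes above background everywhere, 2 with no filter, 39 with the trend, 69 at 0.10, 0 with the floor, 2 with all features and 11 without X and Y genes, and 0 to 273 with 1 array left out. The 19 for JAK2V617F became 225, 6, 234, 0, 146, 165, 0 and 1 in the same order up to all features, and 0 to 297. Within MEP the 80 for Ezh2 deletion became 49 with normexp, 53 with quantile normalization, 2 with no filter, 134 with the trend, 139 at 0.10 and 0 with the floor, and 0 to 401. The 20 for JAK2V617F became 54 with normexp, 100 on genes above background everywhere, 0 with no filter, 1.1e+02 with the trend (62 higher and 45 lower), 77 at 0.10 and 0 with the floor, and 0 to 339. Fits within a cell type that leave out 1 array have 1 residual degree of freedom, and the lone array of an arm is assumed to vary like the others. The genes called within a cell type changed too. With normexp 8 of the 55 for Ezh2 deletion in LSK were called at first, and 13 of the 225 for JAK2V617F. In MEP it was 30 of 49 and 8 of 54. On genes above background everywhere it was 2 of 48 and 3 of 234 in LSK, and 13 of 75 and 3 of 100 in MEP. That filter leaves most of the genes first called untested.

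The 1 gene whose Ezh2 effect differed by cell type was lost with normexp, on genes above background everywhere, with no filter, with the floor and with all features (0 each), and there were 6 with quantile normalization, 11 at 0.10 and 0 to 138 with 1 array left out. For the JAK2V617F effect by cell type the 0 became 32 on genes above background everywhere, and 0 to 156. For the Ezh2 effect by JAK2 genotype the 0 became 14 with normexp, 9 on genes above background everywhere, 5 with the trend and 1 with all features, and 0 to 11.

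Counts of genes 2-fold apart between single arrays moved with normexp and with the fold threshold. In LSK, normexp gave 300 genes for Ezh2-deleted against WT, 501 for JAK2V617F, 411 for the double mutant, and 292 and 315 for the double mutant against JAK2V617F and against Ezh2-deleted. In MEP it gave 252, 276, 657, 631 and 290 in that order. A 1.5-fold threshold gave 2176, 3214, 3171, 1992 and 2847 in LSK and 1464, 1636, 4259, 4865 and 3033 in MEP, and a 3-fold threshold gave 209, 355, 311, 261 and 214, and 210, 231, 397, 276 and 233. Genes apart in both pairs were 79 and 150 in LSK and 68 and 76 in MEP for Ezh2 deletion and JAK2V617F with normexp, 752, 1511, 573 and 442 at 1.5-fold, and 65, 76, 62 and 63 at 3-fold.

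Of the gene lists called with camera, 11 for Ezh2 deletion, 14 for JAK2V617F and 10 for MEP against LSK, 0 held with an estimated correlation, nor did any within LSK or MEP. With fry there were 2, 2 and 16, then 1 and 1 for Ezh2 deletion in LSK and MEP and 0 and 0 for JAK2V617F. For JAK2V617F in LSK the 14 lists became 9 on genes above background everywhere, 6 with no filter and 6 with the floor, and in MEP 14 became 9 on genes above background everywhere. Leaving out 1 array gave 7 to 12 lists for Ezh2 deletion, 2 to 12 for it in MEP and 6 to 13 for JAK2V617F in MEP. The direction given by camera reversed for B cell genes with JAK2V617F on genes above background everywhere (0.12, adjusted p = 0.556) and for lymphoid priming genes with JAK2V617F in MEP and the floor (0.00, adjusted p = 0.942). Granulocyte genes for Ezh2 deletion in LSK ran from -1.02 without the WT or Ezh2-deleted LSK array to 0.11, reversed, without the JAK2V617F or double mutant LSK array. Immediate early genes reversed for Ezh2 deletion in LSK without the WT or Ezh2-deleted LSK array (-0.27, range to 0.15). They did so for it in MEP without the JAK2V617F or double mutant MEP array (0.59, range from -0.92), and for JAK2V617F in MEP without the WT or JAK2V617F MEP array (-0.33, range to 1.20). With the floor the granulocyte median for Ezh2 deletion turned from 0.25 to -0.15 and was no longer called (adjusted p = 0.119), while B cell genes (1.00), lymphoid priming genes (0.85) and fetal genes (0.66) stayed called, as did granulocyte genes for JAK2V617F (2.22).

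Quantile normalization moved the median of all genes by -0.11 for MEP against LSK and by 0.12 for the JAK2V617F effect by cell type. Of the genes called for JAK2V617F in MEP 75% were higher, against 48.1% with normexp, and of those called for Ezh2 deletion in MEP 58.5% were higher with quantile normalization, against 75%. With each array left out in turn, named genes for MEP against LSK kept direction and call in all 128 comparisons. Of the 144 comparisons for named Ezh2 genes 65 lost the call, as did 119 of 192 for JAK2V617F, with 0 reversals. With the floor 13 of 18 named Ezh2 genes and 24 of 24 JAK2V617F genes lost the call.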

Other observations

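Tests between the probes of a gene and of single bright spots were chosen only after the result was seen.

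On the WT MEP array 10 genes were at least 16-fold brighter than on each other MEP array, and on the Ezh2-deleted MEP array 7 were. The other arrays had at most 3. Orc5 was at 9.30 on the WT MEP array and at most 0.67 on the other MEP arrays. Mafg was at 9.71 against 4.65, while its other probes differed by -0.15. Spin2d was at -0.08 against -4.77, and its other probe differed by -5.95.

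Of the 93 genes called for Ezh2 deletion 15 had another measured probe, and in all 15 it moved the same way, with a gap of over 1 on the log2 scale in 6. Of the 41 for JAK2V617F 10 had one, 9 moved the same way and 1, Srgap3, moved the opposite way.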
